A study of Mus musculus with 12 samples.

How the data were processed

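Total RNA was extracted with a column kit and made into stranded TruSeq libraries per the labels, from 9 mammary tumours of genotype Trp53R245W/+ and from 3 preparations of wild-type mammary epithelium. Each library came as deposited counts per gene, raw whole numbers with no normalization, and the authors gave 5 further summary counts per library for alignments outside genes, ambiguous, of low quality, not aligned or not unique. The submitters' processing notes name FastQC 0.11.8, TopHat2 2.1.1, HTSeq 0.11.0 and the build GRCm38, without the annotation release, the strand setting or whether reads or read pairs were counted, which are not given in the sources used here. The labels do not say whether each tumour came from a different mouse. The group and replicate number of each library were read from its title. The prefix of the title, R597 for tumours and R688 for epithelium, coincides with the group.

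The files held 54658 genes by symbol, of which 54106 matched a gene of GENCODE mouse release M21, used for positions, gene types and exonic length. Library totals ran from 19695318 to 33600076 gene counts, so a count of 3, taken as the limit that a count of 0 allows, was 0.089 to 0.152 CPM. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries were copies: the smallest chi-square per degree of freedom between 2 libraries of a group was 26.65 in epithelium and 243.38 in tumours.

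Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr on the group, trimmed mean of M values normalization, quasi-likelihood F test with robust fitting), limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The design held the group only. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and SE was taken as the absolute log2 fold change over the square root of F. CPM of single libraries carry no prior count, and list scores are means of log2 CPM with a prior count of 2. The pipeline was tested on simulated data of 12 libraries in the same groups, where it recovered 2% of 50 genes changed 2-fold, 44% at 4-fold, 62% at 8-fold and 92% at 16-fold, with 2 false calls among 102. The simulation gave both groups the same dispersion for each gene and changed few genes, so these shares need not hold for the real data. DESeq2 was run without a filter and gave no adjusted p for 10586 of 38829 genes.

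The comparison, its test, the alternatives (apart from those listed below as added), 30 gene lists and the rule for named genes were chosen before the data were examined. Of the lists, 18 covered cell programmes and 12 covered other cell types that the tissue could hold. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation and with fry, adjusted over the 30 lists, and members were counted as called over all genes and adjusted over the list alone. Genes were named by this rule: genes fixed by name, among them Trp53, Cdkn1a and Mdm2; the 6 largest rises and the 6 largest falls among called genes with a mean of at least 10 CPM in the higher group, no overlap between the groups and a symbol that was not a predicted model, a receptor segment or mitochondrial; from each programme list the 2 called members with the smallest adjusted p in the main direction and the 1 in the other direction, or the 2 most abundant where none was called; from each cell type list 1 member; and oncogenes and receptors in which Dixon's test marked a single tumour. The rule gave 71 genes, of which a few are not reported here. Other list members named as examples, Met, Irs2, Insr and the members of the lists of the closing part were chosen after their values were seen.

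Relations between scores used Pearson's r and Spearman's rho with exact permutation over all 362880 pairings of 9 tumours, two-sided and adjusted over 6 relations, leaving out of both scores any gene shared by both lists. Spread within groups was described by the common dispersion of each group fitted alone. Dixon's ratio with the critical value 0.493 marked single tumours in 71 genes and 30 list scores. Shares of alignments were compared by exact permutation over all splits into 9 and 3 libraries. In the scan along chromosomes, each of 11095 genes with at least 5 CPM was compared with the median of the other 8 tumours. Consecutive windows of 11 genes whose median passed 1.5 on the log2 scale were joined into runs, which can overlap. The runs that arise when neighbouring genes are independent were taken from 200 shuffles of gene order. Shuffles do not keep the shared expression of neighbouring genes.

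Alternatives chosen beforehand were relative log expression or upper quartile scaling, scaling factors without the 50 most abundant genes, no filter on low counts or at least 10 counts in 9 libraries, leaving out each library, DESeq2, limma-voom with a quality weight per group, a test against a 1.5-fold change, scaled list scores, and a prior count of 0.5. Added after seeing the data were a fit to protein-coding genes only, the share of alignments outside genes as a covariate, an offset for gene length, and list counts without tumour 4. No library was left out of the fits reported as the result.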

Results

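RNA sequencing measured gene expression in 9 mouse mammary tumours and in 3 preparations of mammary epithelium enriched from the glands of the same cohort. The tumours carried the genotype Trp53R245W/+ per the labels, a missense change (R245W) in 1 allele of the tumour suppressor p53, and the epithelium was wild-type. Genotype thus followed the group, so effects of the p53 change and of tumour state could not be told apart in any gene or list. All animals were female F1 hybrids of C57BL/6J and BALB/cJ. The comparison asked which genes and pathways differed between p53-mutant mammary tumours and mammary epithelium, and the series title pointed to PI3K-Akt-mTOR signalling and to driver events that differ between tumours. Tumours are named here by the numbers in their labels, which were 1, 4, 5, 14, 17, 20, 21, 24 and 27, and epithelium libraries by 1, 2 and 3. Values are mean ± SD in counts per 1000000 (CPM, scaled by trimmed mean of M values) over 9 tumours and 3 epithelium libraries, and log2 fold changes are tumour over epithelium with their standard error (SE) and edgeR adjusted p.

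The counts in genes were 24353544, 24247566 and 25543872 in epithelium libraries 1, 2 and 3. In the tumours, in the order of their numbers, they were 33600076, 19695318, 31042312, 28612599, 23832833, 24624267, 21936503, 26044794 and 26528767. Tumour 4 stood apart, with 51.97% of its alignments not unique, 22.58% of its gene counts in the small nuclear RNA gene Rn7sk and 11.17% in mitochondrial genes. Alignments outside annotated genes made up 23.24% ± 6.43 in tumours and 40.91% ± 0.88 in epithelium. The groups did not overlap in this share, so fits that used it as a covariate could not separate its effect from that of the group. The share of alignments that were not unique did not overlap either and was higher by 15.12 points in tumours (exact permutation p = 0.00909 for each, two-sided, the smallest that 9 against 3 libraries allow). The title prefix of the libraries, R597 or R688, also separated the groups, so a batch and the group could not be told apart.

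Trp53 itself, on chromosome 11 (69580359 to 69591873, GRCm38), was expressed at 48.5 ± 19.7 CPM in tumours and 43.8 ± 2.0 CPM in epithelium, a log2 fold change of 0.15 (SE 0.37, adjusted p = 0.799). In single tumours it ranged from 18.5 CPM in tumour 4 to 80.9 CPM in tumour 20, and in epithelium from 41.7 to 45.7 CPM. Of 32 p53 target genes, 2 were higher and 4 were lower in tumours, and 2 and 6 when adjusted over the list alone. Btg2, an antiproliferative gene that is also an immediate early gene, fell (log2 fold change -4.08, SE 0.38, adjusted p = 3.9e-05). The other members that fell were Gdf15, a stress-induced cytokine (-3.11), Ddb2, a DNA damage sensor (-0.86), and Trp53inp1 (-1.86). Those that rose were Ei24 (0.88, SE 0.22, adjusted p = 0.0147) and Psrc1, a spindle protein gene (3.55). Cdkn1a, which encodes the cell cycle inhibitor p21, had 18.4 ± 17.6 CPM in tumours and 20.6 ± 1.6 CPM in epithelium (adjusted p = 0.896). Mdm2, the gene of the ubiquitin ligase that degrades p53, had 52.3 ± 13.0 against 85.1 ± 1.5 CPM and lay below every epithelium library in all 9 tumours, but missed the threshold (log2 fold change -0.70, adjusted p = 0.0548). The list's median log2 fold change was -0.12, with a camera adjusted p of 0.265. Without any 1 epithelium library no member was called higher and 2 were called lower, without tumour 4 or 27 there were 7 lower, and without tumour 4, 17, 20, 24 or 27 there was 1 higher. Ei24 reached an adjusted p of 0.0856 when an epithelium library was left out. Ddb2, Trp53inp1 and Psrc1 lost their calls without any 1 epithelium library (adjusted p up to 0.0752, 0.144 and 0.168), Trp53inp1 also without tumour 5, 14 or 17 and Psrc1 without tumour 4, 17, 20, 24 or 27 (adjusted p up to 0.0534 and 0.0649). No p53 target was higher and 2 were lower with the share of alignments outside genes as a covariate (median 0.01). DESeq2 called 10 members of the list and limma-voom 18. DESeq2, limma-voom and upper quartile scaling did call Mdm2 lower, with adjusted p of 0.0213, 0.00121 and 0.0307. So did edgeR in 3 of the fits that left out 1 library.

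Across all genes, 1908 were higher and 2438 lower in tumours of 21456 tested, 20.3% in all, and 1773 and 2302 of these changed at least 2-fold. Among the largest rises was Cdkn2a, which encodes the tumour suppressors p16Ink4a and p19Arf (chromosome 4, 89274471 to 89294653). It went from 0.253 ± 0.123 CPM, 22 counts over the 3 epithelium libraries, to 44.6 ± 31.6 CPM (log2 fold change 7.44, SE 0.85, adjusted p = 0.00011) and was raised in every tumour. Col2a1, the collagen of cartilage (33.4 CPM, log2 fold change 8.62), Tnn, a matrix glycoprotein (46.9 CPM, 8.76), Car6, a secreted carbonic anhydrase (183.6 CPM, 11.53), H2-Q1, a class I histocompatibility gene (10.6 CPM, 7.71), and Rprl2, a gene of a ribonuclease P-like RNA (16.5 CPM, 6.96), completed the 6 largest rises chosen by rule. Each of these 5 rested on 4 to 11 epithelium counts in all, so their folds are imprecise. H2-Q1 has close paralogs that can share reads, and 1 tumour dominated Car6 (tumour 14, 1271 CPM), Tnn (tumour 21, 356 CPM) and Rprl2 (tumour 4, 86.2 CPM). Without these tumours the log2 fold changes were 9.58, 6.25 and 5.90. Without epithelium library 1 that of Car6 was 12.19, without library 2 those of Col2a1, H2-Q1 and Rprl2 were 9.22, 8.91 and 11.74, and without library 3 that of Rprl2 was 6.38. The largest fall was that of Glycam1, a mucin of high endothelial venules and of milk (chromosome 15, 103562759 to 103565081), from 820 ± 214 to 0.604 ± 0.598 CPM (log2 fold change -10.37, SE 0.83, adjusted p = 1.6e-05). Other large falls were those of Marco, a scavenger receptor of macrophages (63.3 to 0.165 CPM), Il22ra2, a soluble receptor for interleukin-22 (18.3 to 0.060 CPM), the immediate early gene Fosb (698 to 3.12 CPM) and Dmbt1, a secreted mucosal protein gene (328 ± 469 to 1.74 CPM). Epithelium library 3 carried the Dmbt1 mean with 869 CPM, and without it the log2 fold change moved from -7.56 to -5.07. The median log2 fold change of all genes was 0.17, or 0.07 under upper quartile scaling, and changes are to be read relative to it. This baseline varied with gene length. For protein-coding genes the median ran from 0.824 in the shortest of 10 length classes to -0.076 in the longest. Leaving out epithelium library 1, 2 or 3 lowered the genes called higher to 506, 541 or 548 and those called lower to 1499, 1542 or 1496. The share called higher then moved from 43.9% to between 25.2% and 26.8%, and Car6, Tnn and Rprl2 lost their calls (adjusted p up to 0.117, 0.108 and 0.0551). With the share of alignments outside genes as a covariate, 202 genes were higher and 456 lower. Since this share did not overlap between the groups, such losses of calls do not set it apart from the group.

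Genes of cell division rose together in the tumours. Of 28 mitosis genes 27 were higher and none lower, with the same counts adjusted over the list alone. Kif20a, a kinesin of cytokinesis, went from 8.18 ± 0.77 to 95.2 ± 43.8 CPM (log2 fold change 3.54, SE 0.47, adjusted p = 0.00028), and Cenpf, a kinetochore protein gene, from 11.98 ± 3.26 to 176 ± 98 CPM (3.88, SE 0.56, adjusted p = 0.00044). The proliferation marker Mki67 rose from 81.5 ± 26.3 to 632 ± 505 CPM and the mitotic kinase gene Plk1 from 2.21 to 40.0 ± 36.1 CPM. Of 28 genes of DNA replication and E2F targets 21 were higher and none lower, and 24 higher adjusted over the list alone. They included E2f1, a transcription factor of the G1 to S phase transition (1.73 to 15.8 CPM, log2 fold change 3.19, SE 0.62), and Cdc45, a part of the replicative helicase (4.04 to 29.9 CPM, 2.89, SE 0.61). The median log2 fold changes were 3.10 for mitosis and 1.83 for replication, with camera adjusted p of 1.4e-19 and 2.4e-09 at the preset correlation and adjusted p of 0.283 and 0.357 with an estimated correlation and 0.0034 and 0.0104 with fry. The replication count fell to 7, 6 or 8 without epithelium library 1, 2 or 3, and Mki67 lost its call without library 1 or 2 (adjusted p of 0.0596 and 0.0554). With the share of alignments outside genes as a covariate, 1 gene of each list was called, while the medians were 3.31 and 2.32 and both lists passed camera at the preset correlation (adjusted p of 2.4e-11 and 4.4e-06). In that fit neither passed with an estimated correlation (0.440 and 0.565) or with fry (0.100 and 0.142).

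**Figure D1:**
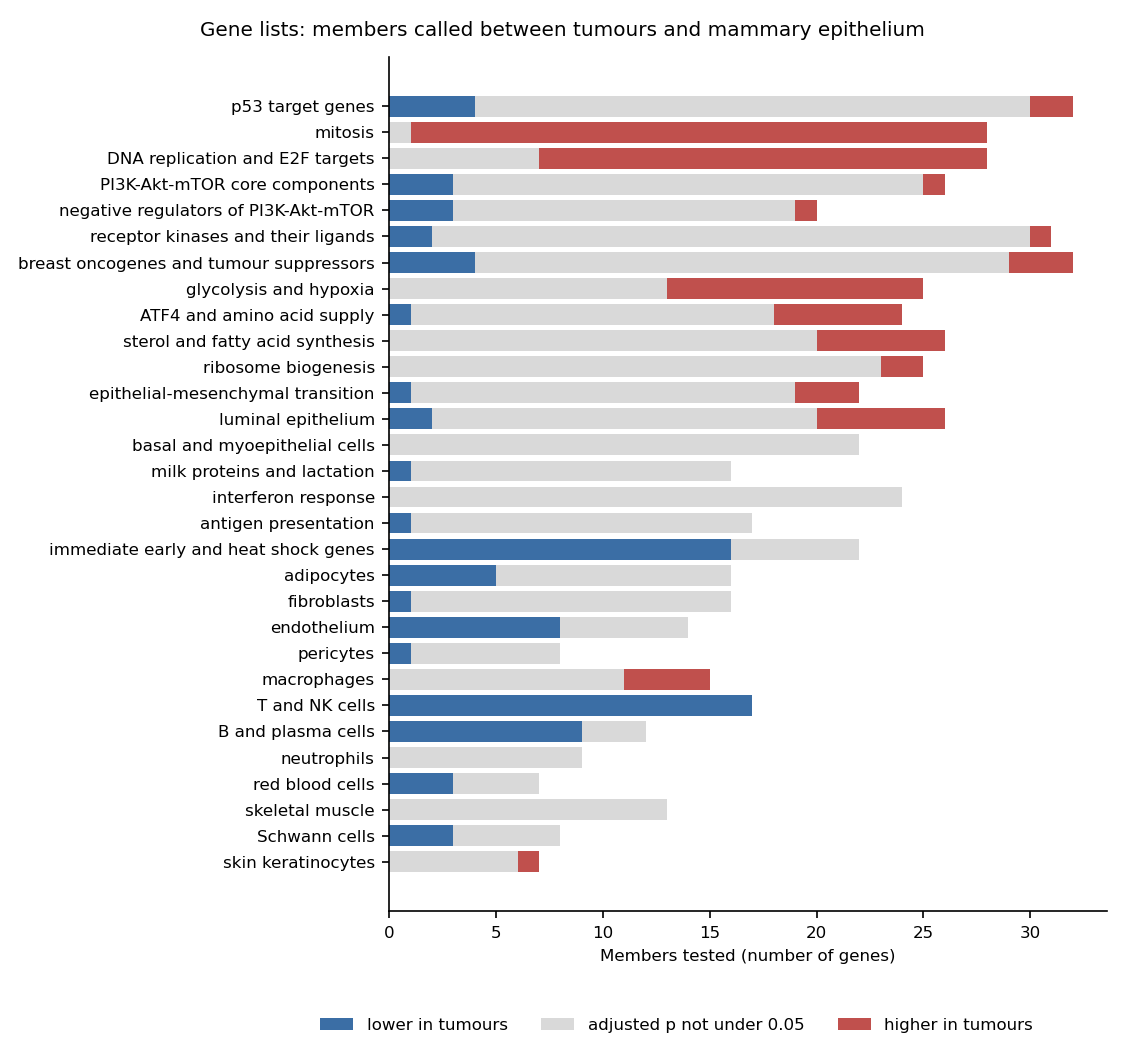
Members of 30 gene lists tested between 9 tumours and 3 epithelium libraries, with the number of genes on the x axis and 1 bar per list, split into members lower in tumours (blue), members whose adjusted p was not under 0.05 (grey) and members higher in tumours (red). Mitosis had 27 of 28 members higher and T and NK cells had 17 of 17 lower.

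The PI3K-Akt-mTOR pathway, which passes growth factor signals on to cell growth, differed in the RNA of a few genes, and neither of its lists passed camera. In each list 4 members were called, no larger a share than the 20.3% called over all genes tested. Only RNA was measured, so the activity of the pathway was not tested. Of 26 core components 1 was higher and 3 were lower, and the same adjusted over the list alone. Those that fell encode subunits of PI3 kinase found mainly in leukocytes. They were the catalytic subunits Pik3cd (chromosome 4, 149649168 to 149702571; 160 ± 19 to 28.01 ± 16.5 CPM, log2 fold change -2.52, SE 0.40, adjusted p = 0.00089) and Pik3cg (74.8 ± 3.0 to 26.8 ± 12.9 CPM, -1.48, SE 0.42), and the regulatory subunit Pik3r5 (-1.65). Genes of T and NK cells, which are leukocytes, had a median log2 fold change of -4.81 in the same tumours. Eif4ebp1, the translation repressor that mTOR phosphorylates, rose from 11.3 ± 1.7 to 53.5 ± 37.0 CPM (2.24, SE 0.60, adjusted p = 0.0208). Of 20 negative regulators 3 were lower and 1 was higher, and the same adjusted over the list alone. Inpp4b, a phosphatase that removes a PI3 kinase product (chromosome 8, 81342556 to 82127914), fell from 238 ± 2.5 to 27.8 ± 32.0 CPM (-3.10, SE 0.62, adjusted p = 0.0040). Inpp5d, the leukocyte phosphatase SHIP1, fell from 144 ± 8.4 to 53.03 ± 25.0 CPM (-1.44), and the transcription factor gene Foxo1 fell as well (-1.08). Akt1s1, an mTOR inhibitor that Akt phosphorylates, rose from 17.5 ± 0.6 to 49.4 ± 15.7 CPM (SE of the log2 fold change 0.34, adjusted p = 0.0084). Median log2 fold changes were 0.17 for the core and -0.05 for the negative regulators, with camera adjusted p of 0.798 and 0.668. Without any 1 epithelium library 1 core gene and 1 negative regulator were called lower and no core gene higher. Also, none of the negative regulators was higher without library 1 or 2, and without tumour 4 or 21 there were 2 core genes higher. Without an epithelium library Pik3cg, Eif4ebp1, Inpp5d and Akt1s1 reached adjusted p of up to 0.0919, 0.0957, 0.0671 and 0.0509. Without tumour 1 the log2 fold change of Inpp4b was -3.75. Pik3r5 and Foxo1 lost their calls without any 1 epithelium library (adjusted p up to 0.103 and 0.109). No member of either list was called by edgeR with the share of alignments outside genes as a covariate (medians 0.20 and 0.56). DESeq2 called 5 core genes and 6 negative regulators, and limma-voom 10 and 8.

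**Figure D2:**
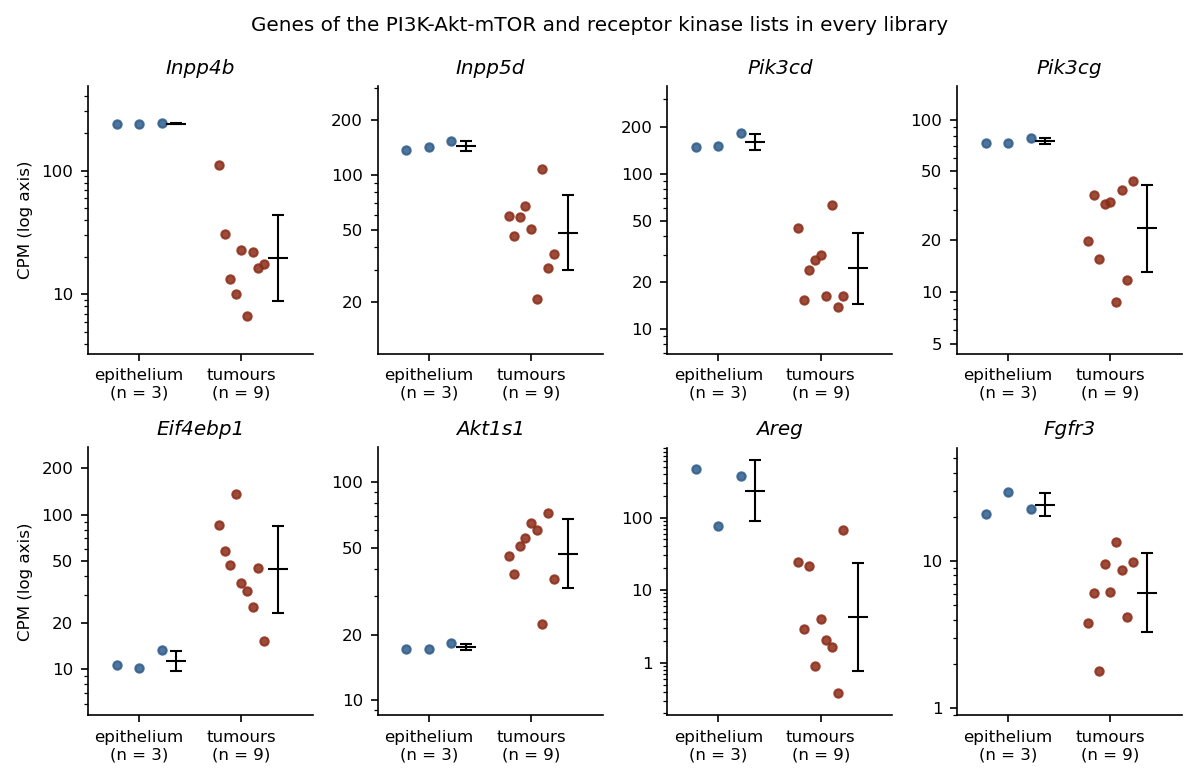
CPM on a log axis for 8 genes of the PI3K-Akt-mTOR lists or the list of receptor kinases and ligands in each library, with 1 point per library, 3 epithelium libraries and 9 tumours, and bars for the mean and SD of log2 CPM. Inpp4b, Inpp5d, Pik3cd, Pik3cg, Areg and Fgfr3 were lower and Eif4ebp1 and Akt1s1 were higher in every tumour than in any epithelium library.

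Few growth factor receptors and ligands upstream of this pathway passed the test in edgeR, and more did in other tools. Of 31 receptor kinases and ligands 1 was higher and 2 were lower, and the same adjusted over the list alone. Areg, the EGF receptor ligand amphiregulin, fell from 302 ± 201 to 13.99 ± 22.3 CPM (log2 fold change -4.43, SE 1.16, adjusted p = 0.0182). Fgfr3 fell from 24.5 to 7.07 CPM (-1.79), and the collagen receptor gene Ddr1 rose from 36.0 ± 5.7 to 93.9 ± 32.0 CPM (1.38). DESeq2 called 9 members and limma-voom 16. The list's median log2 fold change was 0.38 while camera put the list lower (adjusted p = 0.987). Of 32 breast oncogenes and tumour suppressors 3 were higher and 4 were lower, or 4 and 5 adjusted over the list alone. Besides Cdkn2a, the neighbouring cell cycle inhibitor gene Cdkn2b (4.07) and Hras (1.67) rose. The inhibitor of apoptosis genes Birc3 (195 ± 6 to 42.9 ± 15.6 CPM, -2.18, SE 0.29, adjusted p = 0.00025) and Birc2 (134 to 45.3 CPM, -1.57), the p53 inhibitor gene Mdm4 (-1.21) and the histone methyltransferase gene Kmt2c (-0.85) fell. This list had a median of 0.17 and a camera adjusted p of 0.806, and DESeq2 called 13 members and limma-voom 21. Without any 1 epithelium library the receptor list had 0 higher and 1 lower and the oncogene list 1 higher. Fgfr3, Areg and Ddr1 lost their calls in at least 1 of these fits (adjusted p up to 0.0790, 0.0773 and 0.101). Without tumour 4, 5 or 24 there were 2 receptor genes higher, without tumour 21 there were 5 lower, and without tumour 4 there were 5 oncogene list members higher. The log2 fold change of Areg was -5.39 without tumour 27. Cdkn2b, Hras and Kmt2c lost their calls without any 1 epithelium library (adjusted p up to 0.0656, 0.0727 and 0.0628), and Cdkn2b had a log2 fold change of 3.43 without tumour 1. The covariate of alignments outside genes left no receptor or ligand called (median 0.84), and 2 oncogene list members higher and none lower (median 0.31).

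Metabolic genes that rose were those of glycolysis and, in smaller numbers, of amino acid and sterol synthesis. Genes of other cells fell in the same comparison, with medians of -4.81 for T and NK cells and -1.48 for endothelium. These rises are therefore not shown to occur within epithelial cells. Of 25 genes of glycolysis and hypoxia 12 were higher and none lower, or 15 higher and 1 lower adjusted over the list alone. Gapdh rose from 152 ± 25 to 919 ± 210 CPM (log2 fold change 2.60, SE 0.32, adjusted p = 0.00017) and Tpi1 from 112 ± 12 to 565 ± 274 CPM (2.34, SE 0.44), both of them enzymes of glycolysis. Car9, a hypoxia-induced carbonic anhydrase, rose by 4.31 on the log2 scale. Of 24 genes of ATF4 and amino acid supply 6 were higher and 1 was lower, or 11 and 1 adjusted over the list alone. Among them were the proline synthesis gene Pycr1 (1.77 to 12.7 CPM, 2.84), Trib3, a target of ATF4 (2.95 to 25.2 CPM, 3.10), and, falling, the glutamine transporter gene Slc1a5 (68.6 to 27.3 CPM, -1.33). Of 26 genes of sterol and fatty acid synthesis 6 were higher and none lower, or 9 higher adjusted over the list alone, with the cholesterol synthesis genes Sqle (31.2 to 99.8 CPM, 1.68) and Dhcr7 (8.26 to 36.3 CPM, 2.14). Of 25 ribosome biogenesis genes Ncl (146 to 405 CPM, 1.47) and Pes1 (62.0 to 110 CPM, 0.83) were higher, and 1 adjusted over the list alone. Median log2 fold changes were 1.53, 0.91, 0.88 and 0.68, with camera adjusted p of 1.7e-06, 0.0196, 0.00052 and 0.0126, and adjusted p of 0.340, 0.436, 0.515 and 0.822 with an estimated correlation and 0.0079, 0.0295, 0.0268 and 0.197 with fry. The medians of ATF4, sterols and ribosome biogenesis were of the size of the 0.824 seen in the shortest protein-coding genes. Members of these lists were not compared with genes of like length. Without epithelium library 1, 2 or 3 the counts higher were 7, 6 and 6 for glycolysis, 1, 2 and 1 for ATF4, 1, 2 and 1 for sterols and 0 each for ribosome biogenesis. In these fits Trib3, Slc1a5, Dhcr7, Ncl and Pes1 lost their calls at least once (adjusted p up to 0.0667, 0.0631, 0.0579, 0.0835 and 0.136). Without tumour 4 there were 10 sterol genes and 5 ribosome biogenesis genes higher. Without tumour 21 there were 4 of the latter and 1 glycolysis gene lower, and without tumour 5 or 27 there were 2 ATF4 genes lower. When the share of alignments outside genes was a covariate, 1 glycolysis and 2 ATF4 genes were higher and edgeR called no other member of these lists. The medians of glycolysis, ATF4, sterols and ribosome biogenesis were then 1.91, 2.03, 1.17 and 1.17, and all 4 lists passed camera at the preset correlation (adjusted p of 2.6e-06, 0.0080, 0.0041 and 0.0032). None of these did with an estimated correlation (0.440, 0.440, 0.635 and 0.715) or with fry (0.0762, 0.0766, 0.160 and 0.317).

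Epithelial genes shifted in both directions. Of 26 genes of luminal epithelium 6 were higher and 2 were lower, or 8 and 4 adjusted over the list alone. Regulators and junction proteins of epithelium rose: Grhl2 (42.7 ± 10.7 to 112 ± 25 CPM, log2 fold change 1.39, SE 0.28, adjusted p = 0.0042), Esrp1 (53.6 ± 6.7 to 152 ± 46 CPM, adjusted p = 0.0067), Cldn3 (2.25), Epcam (1.75), Rab25 (1.81) and Cdh1 (1.54). Genes of other cells fell in the same comparison, with medians of -4.81 for T and NK cells, -4.87 for B and plasma cells, -1.48 for endothelium and -1.04 for adipocytes. RNA of such cells in the epithelium libraries lowers the share of epithelial genes there, so these rises are not shown to occur within epithelial cells. The hormone receptor genes fell, Esr1 for the oestrogen receptor from 70.7 ± 21.9 to 10.7 ± 11.8 CPM (-2.72, SE 0.71, adjusted p = 0.0177) and Pgr for the progesterone receptor from 156 ± 97 to 5.76 ± 14.8 CPM (-4.75). Tumour 27 had 38.4 CPM of Esr1 and 45.1 CPM of Pgr, against 0 to 1.84 CPM of Pgr in the other 8 tumours, and without it the log2 fold change of Pgr was -7.54. Epithelium library 2 had only 44.15 CPM of Pgr, against 202.28 and 220.66 CPM in libraries 1 and 3. Tumour 27 thus overlapped the epithelium in Pgr. Of 22 genes of epithelial-mesenchymal transition 3 were higher and 1 was lower, and the same adjusted over the list alone. Spp1, the secreted phosphoprotein osteopontin (18.0 ± 13.3 to 1320 ± 1329 CPM, 6.20, SE 1.42, adjusted p = 0.0089), Timp1, a metalloproteinase inhibitor (3.56), and Tnc, a matrix protein (3.60), rose. The transcription factor gene Zeb1 fell from 131 ± 7.7 to 36.1 ± 24.3 CPM (-1.86). Zeb1 was highest in tumour 21 (97.05 CPM), which also had the highest fibroblast score, so its fall is not shown to occur within epithelial cells. Neither list passed camera, with medians of 0.77 and 0.37 and camera adjusted p of 0.668 and 0.703. Without epithelium library 1, 2 or 3 the luminal list had 2, 3 and 2 higher and 0, 1 and 0 lower and the transition list 0, 1 and 0 higher. Esrp1, Esr1, Spp1 and Timp1 lost their calls in at least 1 of these fits (adjusted p up to 0.0521, 0.0888, 0.0537 and 0.0862). Without tumour 27 there were 8 luminal genes lower, without tumour 5 or 14 there was 1, and without tumour 21 there were 3 transition genes lower. Epcam, Rab25, Cdh1, Pgr and Tnc lost their calls without any 1 epithelium library (adjusted p up to 0.105, 0.117, 0.162, 0.109 and 0.131), and Cldn3 without library 3 (0.0544). Cdh1 also lost it without tumour 5, 14, 17, 21, 24 or 27 and Pgr without tumour 5, 14 or 20 (adjusted p up to 0.0656 and 0.0520). The log2 fold change of Spp1 was 6.91 without epithelium library 2. With the share of alignments outside genes as a covariate edgeR called no member of either list, with medians of -0.01 and 1.77, and the transition list passed camera at the preset correlation (adjusted p = 0.0374) but not with an estimated correlation (0.715) or with fry (0.401). DESeq2 called 14 luminal and 4 transition genes, and limma-voom 17 and 9.

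Basal, milk and skin genes gave few calls in edgeR. Of 22 genes of basal and myoepithelial cells edgeR called none, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05, while DESeq2 called 9 and limma-voom 12. Acta2, the smooth muscle actin of myoepithelial cells, had 304 ± 393 CPM in tumours and 498 ± 33 CPM in epithelium (log2 fold change -0.71, adjusted p = 0.571), with 996 and 993 CPM in tumours 20 and 27. The basal list's median was -0.35 and its mean 0.47 (camera adjusted p = 0.668). Of 16 genes of milk proteins and lactation edgeR called only Glycam1, and the same adjusted over the list alone, while DESeq2 called 6 and limma-voom 5 (median 2.71, camera adjusted p = 0.668). Of 7 genes of skin keratinocytes Sbsn rose (1.80 to 14.01 CPM, 2.96), and 2 did adjusted over the list alone, while DESeq2 and limma-voom called 3 each (median 2.45, camera adjusted p = 0.323). The call of Sbsn was lost without any 1 epithelium library (adjusted p up to 0.118). Leaving out tumour 1 gave 1 basal gene and 2 milk genes higher and 2 milk genes lower, tumour 20 gave 1 basal gene lower and 1 milk gene higher. Leaving out tumour 27 gave 4 basal and 2 milk genes lower, and tumour 1, 20 or 21 gave 2 keratinocyte genes higher. With the share of alignments outside genes as a covariate edgeR called no member of these lists, with medians of 2.28, 0.99 and 6.21, and the keratinocyte list passed camera at the preset correlation (adjusted p = 0.0161) but not with an estimated correlation (0.440) or with fry (0.100).

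Immediate early genes, which cells induce within minutes of a stimulus, were far lower in tumours. Of 22 immediate early and heat shock genes 16 were lower and none higher, or 17 lower adjusted over the list alone. Fos, a subunit of the transcription factor AP-1 (chromosome 12, 85473890 to 85477273), fell from 1649 ± 355 to 22.4 ± 11.2 CPM (log2 fold change -6.20, SE 0.46, adjusted p = 9.1e-06), and Zfp36, which promotes mRNA decay, from 449 ± 96 to 26.2 ± 10.7 CPM (-4.10, SE 0.35, adjusted p = 2.4e-05). Jun (-3.06), Egr1 (-2.77), Atf3 (-5.08), Dusp1 (-3.91) and the heat shock gene Hspa1a (-3.07) fell too. The list's median was -2.54, with a camera adjusted p of 1.3e-16 at the preset correlation and an adjusted p of 0.139 with an estimated correlation and 1.1e-05 with fry. Without epithelium library 2 there were 10 lower, and with the share of alignments outside genes as a covariate there were 5, while the median was -2.10 and the list passed camera at the preset correlation and fry (adjusted p of 9.0e-11 and 0.0150) but not camera with an estimated correlation (0.226). Hspa1a lost its call without any 1 epithelium library (adjusted p up to 0.0970), and its log2 fold change was -3.67 without tumour 24.

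Lymphocyte genes were lower and some macrophage genes higher in the tumours. All 17 genes of T and NK cells were lower, also adjusted over the list alone. Cd5, a T cell receptor regulator, fell from 52.2 ± 1.6 to 0.841 ± 0.651 CPM (log2 fold change -5.95, SE 0.53, adjusted p = 3.1e-05), Cd8a of cytotoxic T cells from 64.7 CPM by a log2 fold change of -5.26 and Foxp3 of regulatory T cells by a log2 fold change of -3.84. Of 12 genes of B and plasma cells 9 were lower, or 10 adjusted over the list alone, among them Cd22 (171 ± 26 to 6.35 ± 4.77 CPM, -4.75, SE 0.50, adjusted p = 7.0e-05) and Ms4a1, which encodes CD20 (-5.54). The medians were -4.81 and -4.87, with camera adjusted p of 1.5e-22 and 2.0e-08 and adjusted p of 0.139 and 0.283 with an estimated correlation and 1.0e-05 and 0.00011 with fry. Of 15 macrophage genes 4 were higher and none lower, or 5 higher adjusted over the list alone. They were Fcgr1, an Fc receptor gene (3.73 ± 1.12 to 23.7 ± 12.8 CPM, 2.67, SE 0.60, adjusted p = 0.0080), and the complement genes C1qa (75.2 to 373 CPM, 2.31), C1qb (2.28) and C1qc (1.83). The macrophage median was 0.93, with a camera adjusted p of 0.0142 and an adjusted p of 0.773 with an estimated correlation and 0.160 with fry. Marco, a macrophage receptor gene outside this list, went the other way, from 63.3 to 0.165 CPM (-8.46). Without epithelium library 1, 2 or 3 there were 0, 0 and 1 macrophage genes higher (adjusted p up to 0.0527 for Fcgr1, 0.0807 for C1qa, 0.118 for C1qb and 0.0854 for C1qc), and with the share of alignments outside genes as a covariate 11 T and NK cell genes and 1 B and plasma cell gene were lower. The medians were then -5.17 and -3.003, and both lists passed camera at the preset correlation (adjusted p of 4.6e-26 and 3.7e-06) but not with an estimated correlation (0.124 and 0.440), and with fry the adjusted p was 0.0057 and 0.0990. With that covariate edgeR called no macrophage gene and the macrophage list, with a median of 1.16, no longer passed camera (adjusted p = 0.275).

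Of 24 interferon response genes edgeR called none, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 4. Ddx58, a sensor of viral RNA, had 116 ± 70 CPM in tumours and 110 ± 5.5 CPM in epithelium, and the interferon regulator gene Irf7 had 103 ± 115 against 30.04 ± 4.2 CPM (median of the list 0.96, camera adjusted p = 0.460). Of 17 genes of antigen presentation edgeR called only Nlrc5, an activator of class I genes, which was lower (174 ± 6.6 to 49.6 ± 38.4 CPM, log2 fold change -1.81, SE 0.55, adjusted p = 0.0355), and none adjusted over the list alone, with 3 at an unadjusted p under 0.05. DESeq2 called 2 members and limma-voom 10. The list had a median of -0.75 and a camera adjusted p of 0.0620, or 0.822 with an estimated correlation and 0.132 with fry. At the preset correlation the list passed camera as lower without epithelium library 2 or without tumour 4, 5 or 27 (adjusted p of 0.0424, 0.0312, 0.0373 and 0.0327), but in none of these fits with an estimated correlation (0.820, 0.818, 0.837 and 0.739) or with fry (0.210, 0.107, 0.151 and 0.0751). Nlrc5 lost its call without any 1 epithelium library or without tumour 14, 17 or 24 (adjusted p up to 0.112). Without tumour 1 there were 2 members lower and without tumour 21 there were 3. In the interferon list 1 gene was higher without tumour 1 or 24. With the share of alignments outside genes as a covariate edgeR called no member of the interferon and antigen presentation lists, whose medians were -1.09 and -1.03, and both passed camera as lower at the preset correlation (adjusted p of 0.00088 and 0.0043) but not with an estimated correlation (0.715 and 0.665) or with fry (0.401 and 0.317). Of 9 neutrophil genes edgeR called none, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 3. Mmp9, a protease of neutrophils, had 50.9 ± 120.5 against 10.1 ± 0.9 CPM, with 371 CPM in tumour 1 (median of the list 2.05, camera adjusted p = 0.521).

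**Figure D3:**
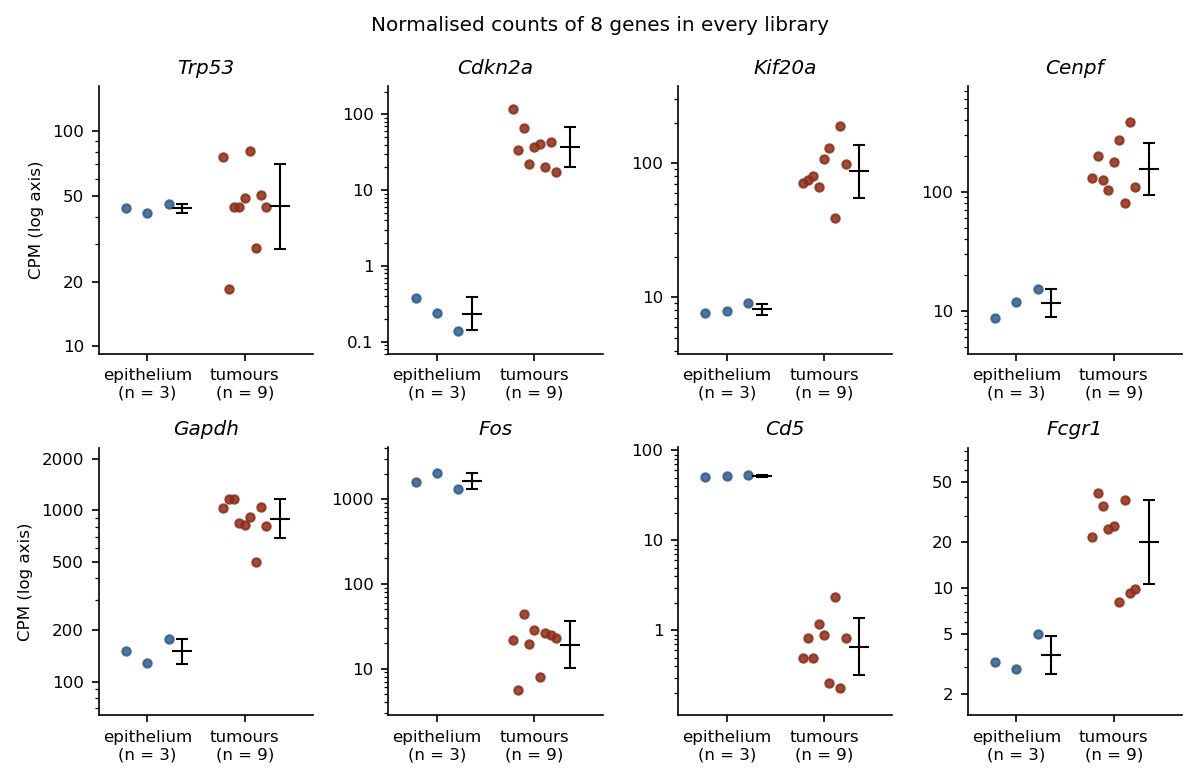
CPM on a log axis for 8 genes in each library, with 1 point per library, 3 epithelium libraries and 9 tumours, and bars for the mean and SD of log2 CPM. Cdkn2a, Kif20a, Cenpf, Gapdh and Fcgr1 were higher in every tumour than in any epithelium library, Fos and Cd5 were lower in every tumour, and Trp53 overlapped.

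A part of the genes of vessels, fat and nerve was lower in tumours. Of 14 endothelial genes 8 were lower and none higher, or 10 lower adjusted over the list alone. They included Tek, the angiopoietin receptor (76.3 ± 5.9 to 12.2 ± 5.5 CPM, log2 fold change -2.64, SE 0.35, adjusted p = 0.00024), and Pecam1 (378 to 88.1 CPM, -2.10). Of 16 adipocyte genes 5 were lower, and the same adjusted over the list alone. They were the fatty acid transporter gene Cd36 (415 ± 85 to 22.1 ± 15.0 CPM, -4.23, SE 0.60, adjusted p = 0.00041), Fabp4 (-3.69), Pparg (-2.62), Lpl (-2.43) and Lipe (-1.33), of which Cd36 and Fabp4 are also expressed in endothelium. Of 8 Schwann cell genes 3 were lower, or 4 lower and 1 higher adjusted over the list alone, and they included the myelin genes Prx (-2.89) and Mbp (164 to 41.1 CPM). Of 7 red blood cell genes the globin genes Hba-a2 (51.8 to 6.76 CPM, -2.93, adjusted p = 0.0156), Hba-a1 (-2.78) and Hbb-bt (-3.22) were lower, and the same adjusted over the list alone. Hba-a1 and Hba-a2 are nearly identical and share reads. Medians were -1.48, -1.04, -1.70 and -1.83 for endothelium, adipocytes, Schwann cells and red blood cells, with camera adjusted p of 1.7e-06, 0.0012, 0.0036 and 0.0142 and adjusted p of 0.357, 0.617, 0.245 and 0.611 with an estimated correlation and 0.0015, 0.0268, 0.00028 and 0.0206 with fry. Without epithelium library 2 there were 4 endothelial genes lower. Without library 1 or 3 there were 0 or 1 red blood cell genes lower (Hba-a2 adjusted p up to 0.0993), without tumour 4 there were 5 of these, and without tumour 1 there was 1 Schwann cell gene higher. Lipe lost its call without any 1 epithelium library, Hba-a1 without library 1 or 3 and Hbb-bt without library 1 (adjusted p up to 0.0964, 0.120 and 0.154). The log2 fold changes of Hba-a2, Hba-a1 and Hbb-bt were -3.59, -3.38 and -4.05 without tumour 20, and that of Hbb-bt was -2.26 without epithelium library 1. Under the covariate of alignments outside genes, 1 endothelial, 3 adipocyte and 1 Schwann cell gene and no red blood cell gene were lower. The medians of the endothelial, adipocyte, Schwann cell and red blood cell lists were then -1.29, -2.24, -2.03 and -1.56, and all 4 passed camera at the preset correlation (adjusted p of 7.4e-05, 1.6e-06, 0.00020 and 0.0013). With an estimated correlation the adjusted p was 0.443, 0.440, 0.124 and 0.440, and with fry 0.100, 0.0990, 0.0057 and 0.100.

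Fibroblast, pericyte and muscle genes gave few calls in edgeR. Of 16 fibroblast genes Dpp4, a marker of fibroblast progenitors, was lower (108 ± 24 to 8.60 ± 10.7 CPM, log2 fold change -3.65, SE 0.71, adjusted p = 0.0033), and the same adjusted over the list alone (median -0.10, camera adjusted p = 0.248). DESeq2 called 4 fibroblast and 3 pericyte genes, and limma-voom 7 and 5. With an estimated correlation and with fry the adjusted p of the fibroblast list was 0.936 and 0.302. Without tumour 21 there were 6 fibroblast genes lower, and the list passed camera as lower at the preset correlation and fry (adjusted p of 0.00069 and 0.0016) but not camera with an estimated correlation (0.329). Without tumour 27 there were 2 lower. The log2 fold change of Dpp4 was -4.38 without tumour 21. Of 8 pericyte genes Des, the intermediate filament desmin, was lower (32.8 ± 2.3 to 5.70 ± 2.43 CPM, -2.52, SE 0.33, adjusted p = 0.00024), and the same adjusted over the list alone, with a median of 0.59 and a camera adjusted p of 0.987; 1 member was higher without tumour 4. Of 13 skeletal muscle genes edgeR called none, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, while DESeq2 and limma-voom called 1 each. Ttn, the sarcomere protein titin, had 83.7 ± 96.2 against 161 ± 69.5 CPM (median of the list 0.77, camera adjusted p = 0.845). Under the same covariate edgeR called no member of these lists (medians 0.53, -0.49 and 0.71).

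The tumours differed far more among themselves than the epithelium libraries did. The median SD of log2 CPM was 0.757 over the 9 tumours and 0.177 over the 3 epithelium libraries, and sets of 3 tumours had a median of 0.605 (0.484 to 0.834). The biological coefficient of variation was 70.6% in tumours, 68.2% without tumour 4, and 19.7% in epithelium. These spreads were described without a test.

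Of 6 relations between list scores tested over the 9 tumours, 1 passed the adjustment. Tumours with higher T and NK cell scores had higher antigen presentation scores (Pearson r = 0.866, exact permutation p = 0.003, adjusted p = 0.017; Spearman rho = 0.9, exact permutation p = 0.002, adjusted p = 0.012). The T and NK cell scores rested on low counts, from -1.85 in tumour 24 to 1.11 in tumour 4, against 4.44 to 4.63 in epithelium. The prior count of 2 shapes scores this low, and tumour 4 was the library whose alignments stood apart. Without tumours 1 and 24, those farthest from the median, r was 0.799 (exact permutation p = 0.011). Without tumour 24 alone r was 0.811 and the relation no longer passed (exact permutation, adjusted p = 0.078). Mitosis scores had r = -0.469 and rho = -0.567 with luminal scores (exact permutation p = 0.197 and 0.121, adjusted p = 0.295 and 0.181), and r = -0.84 without tumours 21 and 24. Without tumour 21 alone r was -0.792 and this relation passed (exact permutation, adjusted p = 0.048). Mitosis and glycolysis scores had r = 0.486 and rho = 0.683 (exact permutation p = 0.18 and 0.05, adjusted p = 0.295 and 0.151), and r = 0.271 without tumours 21 and 24. Macrophage and epithelial-mesenchymal transition scores had r = 0.613 and rho = 0.6 (exact permutation p = 0.08 and 0.097, adjusted p = 0.239 and 0.181), and r = 0.412 without tumours 20 and 21. Luminal and transition scores had r = -0.229 and rho = -0.067 (exact permutation p = 0.534 and 0.88, adjusted p = 0.641 and 0.88), and r = -0.267 without tumours 20 and 27. Trp53 and its target list had r = 0.038 and rho = -0.067 (exact permutation p = 0.918 and 0.88, adjusted p = 0.918 and 0.88), and r = -0.082 without tumours 4 and 20. The labels gave no batch among the tumours.

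Single tumours carried very high levels of known oncogenes, together with a part of their chromosomal neighbours. Nras, a RAS GTPase gene (chromosome 3, 103058285 to 103067914), had 5021 CPM in tumour 17, against 70.1 to 291 CPM in the other 8 tumours and 92.6 ± 0.8 CPM in epithelium. Met, the hepatocyte growth factor receptor gene (chromosome 6, 17463800 to 17573980), was chosen after its values were seen. It had 15546 CPM in tumour 5 and 4887 CPM in tumour 24, against 52.6 to 651 CPM in the other 7 and 83.9 ± 9.4 CPM in epithelium. As group comparisons neither passed (adjusted p = 0.199 for Nras and 0.108 for Met). Against the median of the other 8 tumours, the 5 expressed neighbours of Met within 1 Mb had a median log2 deviation of 4.13 in tumour 5, where 5 of 5 were over 2-fold higher, and of 2.42 in tumour 24, where 4 of 5 were and Cav1 was lower (-1.82). The 14 neighbours of Nras had a median of 1.29 in tumour 17, where 8 of 14 were over 2-fold higher, and Ptpn22 was lower (-0.79) and Hipk1 and Phtf1 deviated by 0.25 and 0.27. A scan of 11095 expressed genes in windows of 11 along the chromosomes, designed after these values were seen, found 4 runs of at least 30 genes. They lay on chromosome 6 in tumour 5 (4600839 to 23052916, 34 genes, median deviation 3.03) and in tumour 24 (3498382 to 30896794, 68 genes, 2.54), on chromosome 3 in tumour 17 (90511034 to 103738001, 98 genes, 2.52), and on chromosome 8 in tumour 14 (3122061 to 18803189, 59 genes, 1.85). The run in tumour 14 held Irs2, an insulin receptor substrate that activates PI3 kinase, at 416 CPM against 18.6 to 157.5 CPM in the other 8 tumours, and the insulin receptor gene Insr at 525 CPM against 65.8 to 499 CPM. Tumour 4, whose alignments stood apart, also had shorter higher runs within this stretch. They spanned 15 genes including Irs2 (median deviation 1.52) and 18 genes (1.91). Runs of any length appeared in 0, 0, 2 and 6 of 200 shuffles of gene order in tumours 14, 17, 5 and 24. Shuffles break up neighbouring genes that share expression, such as the histone genes that formed runs on chromosome 13 in tumours 4 and 20. They therefore understate how often runs arise without a regional change.

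**Figure D4:**
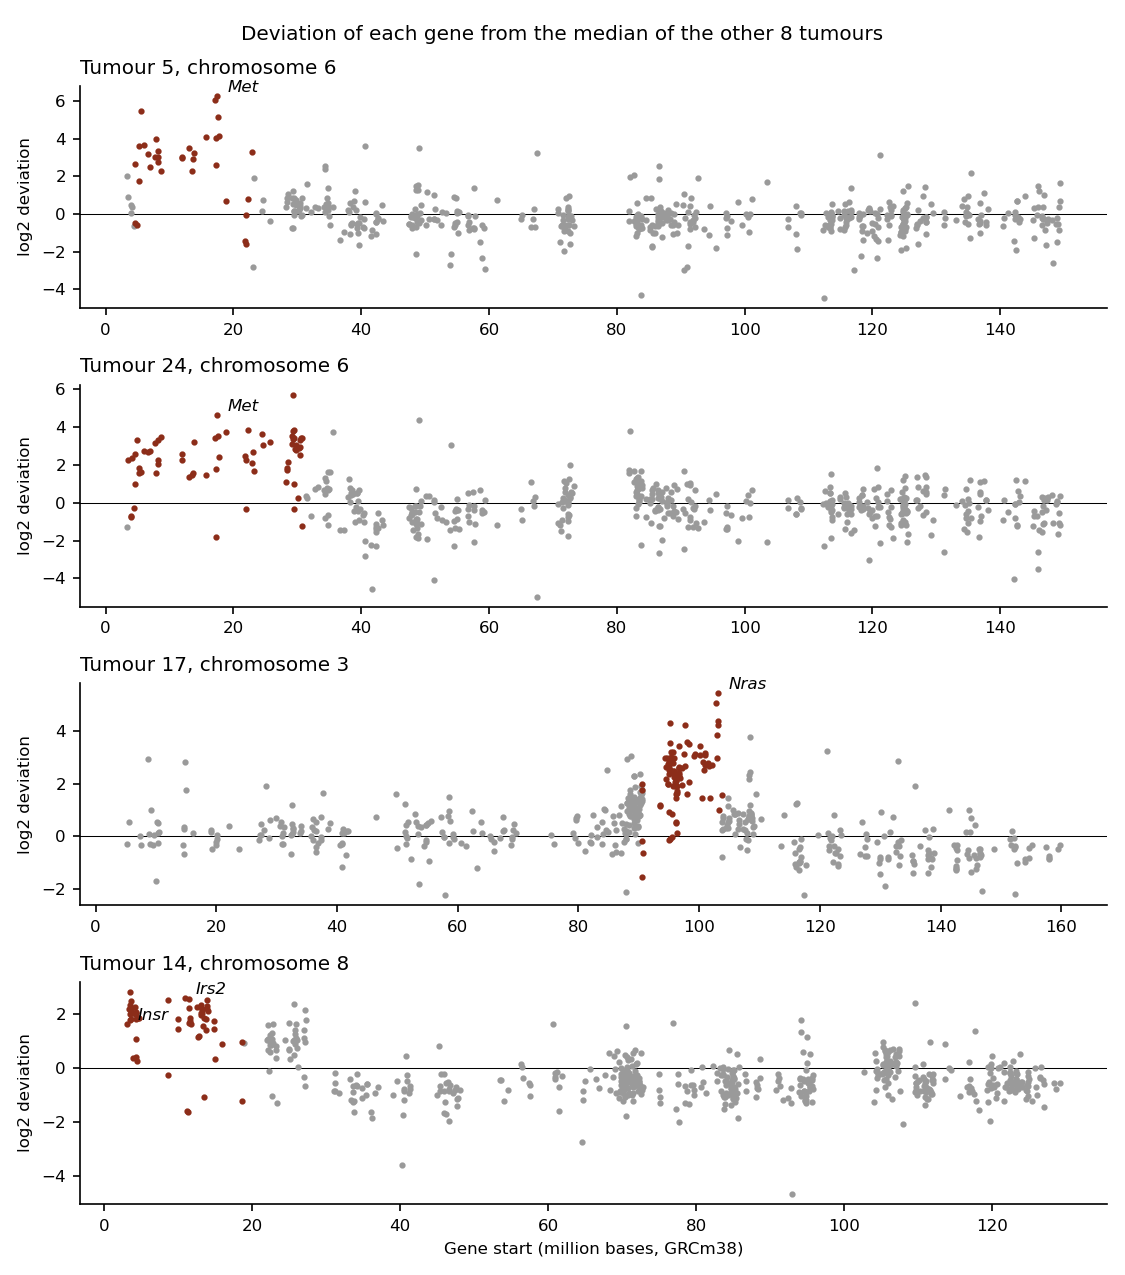
Log2 deviation of each expressed gene from the median of the other 8 tumours (y axis) against gene start in Mb on GRCm38 (x axis), for chromosome 6 in tumours 5 and 24, chromosome 3 in tumour 17 and chromosome 8 in tumour 14, with 1 point per gene and genes of the run in red. The runs held 34, 68, 98 and 59 genes, with median deviations of 3.03, 2.54, 2.52 and 1.85.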

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

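The tests of the gene length trend, of lymph node tissue, of a lower share of other cell types, and of Met and Nras with their neighbours were chosen after the results were seen, while those of a dissociation response and of ERK signalling were chosen before. Dixon's test marked a single tumour far from the other 8 in 10 of 101 genes and lists. Of these, Nras, Ereg, Yap1 and Ncor1 were among the genes only because the test had marked them among 63 receptors and oncogenes. Without them 6 of 97 were marked, where chance flags about 1 in 20 groups, so the number of marks is near what chance gives.

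Tumour 21 was farthest from the others in 4 results, with a fibroblast score of 8.71 on the log2 CPM scale (median of the others 5.51), Tnn at 356 CPM (5.19), Zeb1 at 97.05 CPM (30.84) and Gapdh lowest at 496.2 CPM (969.8). Tumour 4, whose alignments were 51.97% not unique, was farthest in 3, with Rprl2 at 86.21 CPM (median of the others 7.36), Yap1 lowest at 54.64 CPM (139.2) and Ncor1 lowest at 178.5 CPM (294.1). Tumour 27 had a p53 target score of 5.03 (median of the others 4.17). Tumour 1 had Ereg, an EGF receptor ligand gene, at 41.42 CPM (0.602). Tumour 17 had Nras at 5021 CPM (117.5).

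The score of immediate early and heat shock genes was lower in every tumour, with Fos at 22.4 CPM against 1649 CPM in epithelium. ERK signalling induces many of them, and lower ERK signalling in tumours would lower its feedback genes, but the 12 feedback genes had a median log2 fold change of 0.95 (SD over genes 1.38), with Etv4, Etv5 and Phlda1 higher and none lower. Camera did not call the feedback list higher (adjusted p = 0.0586, and 0.581 with an estimated correlation). Dusp5, Spry1 and Spry2 had negative log2 fold changes that were not called. A gene length trend between the groups is argued against, since the list's median stayed at -2.8 after the median of genes of like length was subtracted. A separate list of 19 genes that tissue dissociation induces had a median of -1.68 (SD 1.08), 11 lower and 1, Cebpb, higher (camera adjusted p = 5.5e-08, adjusted p = 0.155 with an estimated correlation). A response to the preparation of the epithelium may account for the pattern. Genes induced together with immediate early genes would also fall with them under another cause. The list thus cannot set such a response apart from a difference between tumour and gland. The labels describe no handling times, and a difference between tumour and gland stays open and untested.

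The scores of T and NK cell and of B and plasma cell genes were lower in every tumour, with median log2 fold changes of -4.81 and -4.87. A lower share of every other cell type in tumours would lower the markers of each alike, but they moved apart. The medians were -1.48 for endothelium (SD over genes 0.620), -1.04 for adipocytes (1.778), -1.70 for Schwann cells (3.271), -1.83 for red blood cells (1.091) and 0.925 for macrophages (0.999), against SDs of 0.882 for T and NK cells and 2.235 for B and plasma cells. The smallest gap to the T and NK cell median, that of red blood cells, was 2.98. The rise of macrophage genes was not called with an estimated correlation (adjusted p = 0.773) or with fry (0.160). An equal fall of every other cell type is thus argued against as the whole of the pattern, while a smaller fall of several other types as a part of it stays open. Mammary glands hold lymph nodes, and 12 genes of lymph node stroma had a median of -6.73 (SD 3.59), 8 lower, with Glycam1 at 820, Cr2 at 205 and Ccl21a at 116 CPM in epithelium (Ccl21a has near-identical copies), so lymph node tissue in the epithelium preparations may account for it. Glycam1 and Marco had been seen before this list was written, and without them the other 10 had a median of -5.17 with 6 called, or -2.78 with 4 of 8 called without Cr2 and Fcer2a, which B cells express too; Glycam1 is also a milk gene. Fewer lymphocytes within the tumours stays open and untested.

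Met in tumours 5 and 24 and Nras in tumour 17 were high together with a part of the neighbouring genes. Scaling of the whole library would raise all genes of a library alike. Values had been scaled and centred on each library's median before this step, so the percentile test could not decide on it. The neighbours lay at percentile 99.05 or above among windows of as many genes of the same library in each of the 3. Their rise was thus not shared by most of the library. The neighbours within 1 Mb had a median log2 deviation of at least 1.29 in each of the 3, so a gain of the chromosome region may account for the pattern, as a hypothesis found and tested on the same data. In tumour 24 the neighbour Cav1 deviated by -1.82, and in tumour 17 there were 8 of 14 neighbours over 2-fold. No DNA copy number was analysed here, and the labels name no driver event per tumour.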

How the results depend on the processing

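Fits to protein-coding genes, with the share of alignments outside genes as a covariate, with an offset for gene length, and list counts without tumour 4 were chosen after seeing the data; the other alternatives were planned. Relative log expression and upper quartile scaling, scaling without the 50 most abundant genes, no filter, and the strict filter kept both counts of called genes within 1.5 times, and kept between 65.5% and 99.1% of the calls. DESeq2 called 3830 genes higher, limma-voom 5006 higher and 5628 lower, the test against 1.5-fold 994 higher, protein-coding genes alone 1140 higher and 1449 lower (fewer genes tested), and the covariate 202 higher and 456 lower, keeping 10% of the calls. The covariate did not overlap between the groups, so calls lost and medians shifted with it do not separate it from the group. Leaving out 1 library gave 506 (without epithelium library 1) to 2486 (without tumour 4) genes higher and 1496 (without epithelium library 3) to 2753 (without tumour 21) lower. With an estimated correlation the adjusted p was 0.2829 for mitosis, 0.3573 for DNA replication, 0.3395 for glycolysis, 0.4364 for ATF4, 0.5145 for sterols, 0.8219 for ribosome biogenesis, 0.1385 for immediate early genes, 0.7734 for macrophages and 0.8219 for antigen presentation, and with fry it was 0.1972 for ribosome biogenesis and 0.1595 for macrophages. None of the 14 lists called at the preset correlation passed with an estimated correlation. With camera at the preset correlation only, antigen presentation passed with no filter (adjusted p = 0.006201), the strict filter (0.01943), protein-coding genes (0.02096), the covariate (0.004323) and the length offset (0.03394), and ranged from 0.03122 to 0.1313 when 1 library was left out. With the covariate epithelial-mesenchymal transition passed (0.03739) and the interferon list turned lower (0.0008775), though with an estimated correlation these and antigen presentation did not pass in that fit (0.7154, 0.7154 and 0.6649). Sets of 3 tumours had a median SD of 0.605. When 1 tumour was left out, r of mitosis with luminal scores ranged from -0.792 to -0.303, and r of T and NK cells with antigen presentation from 0.811 to 0.896, with an adjusted p of 0.078 without tumour 24. Scaled list scores changed no call among the 6 relations, and a prior count of 0.5 left 4 oncogenes and receptors marked. Except for fewer genes or libraries, the cause was not tested.

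Over 71 named genes and 10 other settings, 645 results kept their direction and side of the threshold, 44 lost the call, 15 gained it and 0 reversed; the covariate ended 43 calls. When 1 library was left out, 784 kept both, 63 lost the call, 5 gained it and 0 reversed, and 24 genes lost it at least once. For the 30 lists, the other settings gave 274 unchanged, 17 lost, 7 gained and 1 reversed, and leaving out 1 library gave 355 unchanged and 5 gained. No paired analysis was possible because the groups share only replicate number 1. The simulation recovered 2% of 2-fold changes. It gave both groups the same dispersion for each gene, while the biological coefficient of variation was 70.6% in tumours and 19.7% in epithelium. It also changed a far smaller share of genes than was called here. Its recovery need not carry over to these data, and absent calls at that size say little.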

Other observations

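Both tests of other splits of the libraries were chosen before the result was seen, and the values of single tumours were picked after. Of 100 splits of the 12 libraries into 9 and 3, drawn from 220, 1 called at least as many genes as the real split. This was the real split itself with 4346 genes, and the highest other called 137. The count of genes was thus not reached by any other split drawn. Every other split puts tumours and epithelium into the same group, which widens its spread and lowers its count. A batch that follows the title prefix would pass this test too. For the lists, 46 of the 100 splits called at least as many as the real 14 with camera at its preset correlation, and the highest other called 18, so chance is not excluded for the number of lists called that way.

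Genes of the lists that lay in the long chromosomal runs were not all raised. Asns, asparagine synthetase, had 550.5 CPM in tumour 5 and 589.4 CPM in tumour 24 against a median of 63.2 CPM in the others, and lies in the run on chromosome 6 that holds Met. Phgdh, the first enzyme of serine synthesis, had 261.5 CPM in tumour 17 against 62.3 CPM, and lies in the run on chromosome 3 that holds Nras. The macrophage gene Fcgr1, in the same run of tumour 17, had 25.7 CPM against 23.0 CPM, and the collagen gene Col1a2, in the run of tumour 24, had 588.6 CPM against 681.6 CPM. In all, the scan found 38 runs higher and 28 lower, some of which overlap, so they are not all separate regions. Tumour 4 had 37 runs, against at most 14 in any of 200 shuffles of gene order, of which 197 gave a run, and tumour 1 had 12, against at most 3, with a run in 49 shuffles. As shuffles break up neighbouring genes that share expression, these counts do not show how many of the runs are unusual.

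Protein-coding genes had a median log2 fold change of 0.824 in the shortest of 10 classes by exonic length and -0.076 in the longest, and an offset for length left 0.757 and 0.244.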
